A study of Drosophila melanogaster with 14 samples.

How the data were processed

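RNA was measured in 14 libraries of flies labelled as adult males, 2 in each of 7 genotype groups, with about 50 flies per library. Per the labels, total RNA was enriched on oligo-dT beads, made into libraries with the NEBNext Ultra kit and sequenced as paired ends on an Illumina platform. The labels state no strand marking, so fragments of overlapping and antisense genes could be counted for either gene. The labels describe brains dissected and fixed in paraformaldehyde, and the series description names heads. The submitters' processing notes name the BDGP6 genome, Bowtie2 2.2.3, HISAT2 2.1.0 and TopHat2 without their roles. The tool that computed expression values is not given in the sources used here.

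The authors deposited 3 expression tables with FPKM per gene and library, for the APP groups (14767 genes), the Shal495 groups (14791 genes) and the TrpA1 groups (13312 genes). The tables were deposited separately, list different numbers of genes and share no group, so groups were tested only within a table. The authors also deposited 6 enrichment tables of GO terms and KEGG pathways, which give for each term a p-value, counts of genes and, for the GO terms of APP, a ratio named fold enrichment. Gene identifiers were matched to symbols for 99.1% of genes, and 99.2% of the matched genes had the coordinates of the Ensembl annotation of BDGP6. Library totals were recovered by finding the value per fragment at which FPKM times gene length gave whole fragments, within 0.02 of a whole number. This held for 98.6% to 98.7% of genes per library, and for 97.7%, 97.7% and 97.6% of genes in every library of the APP, Shal495 and TrpA1 tables. Totals were 19255996 and 19660279 fragments in the driver control, 19566061 and 17613024 in the UAS-APP control, 18695359 and 18826488 in elav-Gal4 UAS-APP, 17469057 and 18301767 in w1118, 18146816 and 18292297 in Shal495, 19235298 and 19262368 in elav-Gal4 UAS-TrpA1, and 17162942 and 19911318 in the UAS-TrpA1 control. The detection floor was set at 3 counts per library, and intervals and floors cover counting error only. Replicate pairs were compared with sampling noise by a chi-square per gene, over genes with at least 20 fragments in a pair. It came to 2.27 in the driver control, 23.67 in the UAS-APP control, 1.86 in elav-Gal4 UAS-APP, 24.51 in w1118, 28.1 in Shal495, 3.52 in elav-Gal4 UAS-TrpA1 and 2.33 in the UAS-TrpA1 control, where sampling noise alone gives 1. Replicate numbers did not pair the samples, since differences between replicates correlated across genes at -0.033 to 0.018 between groups of a table.

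Genes with FPKM of 1 or more in at least 2 libraries of a table were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes and a mean-variance trend. Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no fold minimum. The pseudocount of 1 makes fold changes of weakly expressed genes smaller than the ratio of their FPKM. All 3 groups of the APP table shared 1 fit, with 1 error per gene. Replicates of the UAS-APP control spread more than those of the other groups of that table, so errors against that control may be too small. A gene counted as changed against both controls when it passed in both comparisons with one sign. Where the median log2 difference of all tested genes was above 0.1 in size, log2 changes of genes and lists are given less that median. SE is the moderated standard error of the log2 difference, and SD is that of FPKM over the 2 libraries of a group.

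Gene lists, 34 in all, were written from general knowledge of fly genes and cover neuronal, immune, stress, metabolic and cell-type functions, with 1294 members matched and 19 not matched. The sodium channel gene para was among the unmatched. Lists with at least 5 tested members were tested with camera of limma, with a preset correlation between genes of 0.01, two-sided, and adjusted over the lists of a comparison. The same test with the correlation estimated from the libraries called 0 lists in each of the 5 comparisons, where the preset correlation called 22 and 20 for APP against the driver and UAS-APP controls, 22 between these controls, 10 for Shal495 and 16 for TrpA1. Genes named in the text were chosen by a rule. They are the 5 genes Shal, TrpA1, Appl, elav and w in every comparison, the 10 most raised and 10 most lowered genes per comparison with a mean FPKM of 5 or more in a group and no overlap between libraries of the groups, and up to 4 members of each list with the smallest adjusted p that go the way of the list test. Values of a named gene are also given in a comparison where another comparison or list names it. Members that went against their list, or that alone passed in it, are named where 5 or fewer and were chosen after their values were seen. Overlaps between comparisons were tested with one-sided Fisher exact tests and chromosome arms with two-sided Fisher exact tests. Groups, comparisons, threshold, lists, naming rule and most alternatives were fixed before the data were examined. Near-identical genes, such as trypsins, Jonah proteases, amylases, attacins and Hsp70 copies, are reported as single genes as the tables list them, and their values are uncertain.

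Alternatives were a pseudocount of 0.1, no filter, a filter at FPKM 5, median centring, quantile normalization, a fold minimum of 2, the replicate number as a block, fits of only the 2 groups compared, an estimated correlation, leaving out each library in turn, and leaving out genes within 2 Mb of Shal in the test of chromosome arms. The female list was also tested without Cp110 and Cp190 and the male reproductive list without Acp65Aa, which are of other classes, a choice made after seeing the data. Voom on recovered fragments, for genes with at least 10 fragments in 2 libraries, was also added after seeing the data. The procedure was tested on simulated data with a dispersion of 0.005, in which 100 genes changed by a log2 value of 1 and 100 by 2. It recovered 99% to 100% of the changed genes, with 6, 8 and 9 false calls in designs of the APP, Shal495 and TrpA1 tables. That dispersion is lower than the spread between the Shal495 replicates. The list test on simulated data called the raised list and 0 of the other lists. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.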

Results

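Poly(A) RNA of Drosophila melanogaster labelled as adult males aged 5 to 7 days was sequenced in 14 libraries, with about 50 flies behind each. Levels of yolk protein genes and lncRNA:roX2, given below, leave the sex of the flies undecided in some groups. The sample labels name the tissue as brain and the series description names it as head, and the sources used here do not settle which was taken. Gut transcripts in the control libraries of the APP table, given below, argue against either tissue alone there. The libraries form 7 groups with 2 libraries in each (n = 2 throughout), held in 3 expression tables. The first table has flies with the pan-neuronal driver elav-Gal4 alone, flies with a UAS-APP transgene alone, and flies with both. The combination is meant to express the amyloid precursor protein APP in neurons. The second has w1118 flies and flies of the Shal495 line, a mutant of the Kv4 potassium channel gene Shal. The genotype label of Shal495 replicate 2 reads Shal496 where its title reads Shal495, and it was kept in the Shal495 group. The third has flies with UAS-TrpA1 alone and flies with elav-Gal4 and UAS-TrpA1. That combination is meant to express the heat-activated cation channel TrpA1 in neurons, and TrpA1 levels, given below, leave open whether it did. The stated aim was to find pathways downstream of APP, Shal495, TrpA1 and the hyperexcitability of these flies. Library totals recovered from the tables ran from 17162942 to 19911318 fragments, so that the floor of 3 counts for a gene of 1 kb lay between 0.151 and 0.175 FPKM (fragments per kilobase of gene, scaled to the library total). The sources do not say whether the 2 libraries of a group came from separate collections of flies, so p-values measure only the spread between these libraries. That spread was near sampling noise in the driver control, elav-Gal4 UAS-APP and both groups of the TrpA1 table. The chi-square per gene was 1.86 to 3.52 there and 23.67 to 28.1 in the other groups. Where replicates are that close, high counts of genes past the threshold may reflect little spread between libraries rather than many reproducible differences. The tables share no group, and groups were tested only within a table.

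The targeted genes came first (positions on BDGP6, as the tables give them). Shal (3L, 19566851 to 19584568) stood at 19.1 ± 1.20 against 27.4 ± 0.403 FPKM (mean ± SD) in Shal495 against w1118, a log2 change of -0.50 ± 0.093 (SE) that did not pass the threshold (adjusted p = 0.0795). In elav-Gal4 UAS-APP the same gene stood at 32.9 ± 0.901 FPKM, above the driver control at 10.1 ± 0.550 and the UAS-APP control at 17.6 ± 2.11. In elav-Gal4 UAS-TrpA1 Shal was lower than in the UAS-TrpA1 control, 11.7 ± 0.418 against 18.2 ± 0.650 FPKM (adjusted p = 0.000244). TrpA1 (3L, 8894404 to 8904790) was higher in elav-Gal4 UAS-TrpA1 than in the UAS-TrpA1 control, 2.69 ± 0.102 against 1.48 ± 0.000758 FPKM, with a log2 change of 0.74 ± 0.089 after the median shift of all genes was taken away (adjusted p = 0.0019). In the driver control of the APP table, which has no UAS-TrpA1, TrpA1 stood at 2.925 and 2.83 FPKM. It stood at 1.376 and 1.783 in the UAS-APP control and at 1.752 and 1.347 in elav-Gal4 UAS-APP. TrpA1 therefore also differed between lines without that transgene, and the rise above cannot be assigned to the transgene. The species of the APP transgene is not given and its transcript was not analysed here. The fly homolog Appl (X, 530501 to 579044) stood at 168 ± 0.287 FPKM in elav-Gal4 UAS-APP, 9.74 ± 0.335 in the driver control and 36.3 ± 7.66 in the UAS-APP control. The neuronal gene elav (X, 509235 to 523226), whose promoter drives Gal4, stood at 20.5 ± 0.212, 2.32 ± 0.132 and 8.39 ± 2.49 FPKM in these groups. It did not pass the threshold in Shal495 (adjusted p = 0.789) or in elav-Gal4 UAS-TrpA1 (adjusted p = 0.519). The eye pigment transporter gene w (X, 2790599 to 2796466), which is disrupted in w1118, stood at 21.1 and 23.3 FPKM in the Shal495 libraries and at 0.122 and 0.0465 in the w1118 libraries.

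**Figure D1:**
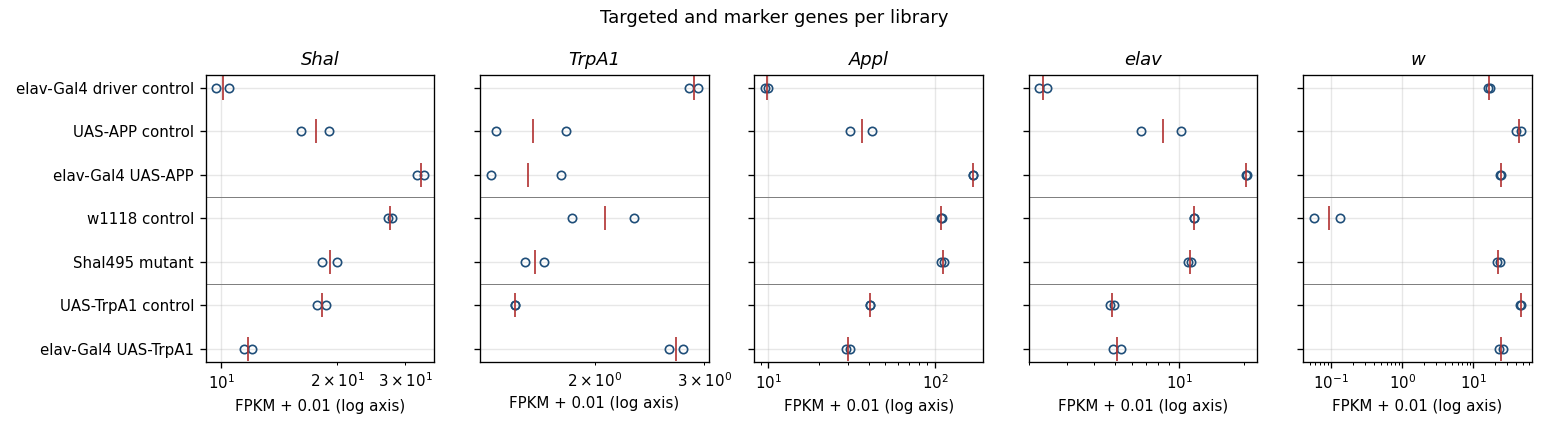
FPKM plus 0.01 of Shal, TrpA1, Appl, elav and w on a log axis, with 1 point per library, grouped by genotype, and a red tick at each group mean. Appl lies near 168 ± 0.287 FPKM in elav-Gal4 UAS-APP and near 9.74 ± 0.335 in the driver control. Levels are not comparable across the 3 tables because these share no group.

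The APP comparison asks which transcripts differ when driver and transgene are combined, against each line that carries only 1 of them. Genes of neurons, synapses and ion channels were higher in elav-Gal4 UAS-APP than in both controls, and genes of digestion, ribosomes and the proteasome were lower. Every list call of the APP comparison was lost with an estimated correlation (adjusted p of 0.169 or more), and the fall of ribosomal protein genes was smaller with quantile normalization (medians of -0.27 and -0.50 in place of -1.76 and -1.67). The nicotinic acetylcholine receptor subunit gene nAChRbeta1 (3L, 4429349 to 4435993) stood at 200.5 ± 1.05 FPKM against 8.67 ± 0.190 in the driver control and 19.8 ± 3.26 in the UAS-APP control. Its log2 changes were 3.95 ± 0.103 and 3.12 ± 0.103, with the SE shared by all groups of the fit although the UAS-APP control libraries spread more. The maltase gene Mal-A8 (2R, 8471954 to 8473961) stood at 4.82 ± 0.142 FPKM against 741 ± 2.78 and 437 ± 21.8, with log2 changes of -7.42 ± 0.06 and -6.40 ± 0.06. The median log2 difference of all 9866 tested genes was 0.43 against the driver control and 0.17 against the UAS-APP control. Log2 changes of genes and lists in the APP comparison are given relative to that median, and counts of genes that rose or fell come from the test on the deposited values. Where 2 changes are given, the first is against the driver control and the second against the UAS-APP control. Single genes that went against their list are named because they are few, and were chosen after their values were seen.

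All 28 tested members of the synaptic vesicle release list rose against both controls, with median log2 changes of 2.80 and 1.53 (adjusted p = 8.66e-07 and 3.05e-07 by the list test). These list calls were lost with the correlation between genes estimated from the libraries (adjusted p = 0.54 and 0.566 with an estimated correlation). The vesicle fusion gene nSyb rose by 3.88 and 1.79, the NSF gene comt by 3.09 and 2.05, and the dynamin gene shi by 2.55 and 1.89. VGAT, which loads GABA into vesicles, rose by 2.82 and 1.84. All 13 members of the neuron list rose as well, with medians of 3.19 and 1.74 (adjusted p = 0.000269 and 0.00034, but 0.54 and 0.566 with an estimated correlation). Among them the active zone gene brp rose by 3.62 and 2.35 and the secreted ligand gene jeb by 3.06 and 2.13. Over the list alone the counts were the same, that is 28 and 13 genes rose when adjusted over the list alone.

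Of 44 tested genes for transmitter receptors and synthesis, 43 rose against either control and ple, the tyrosine hydroxylase gene, fell (-0.70 and -0.77), with the same counts adjusted over the list alone. The list medians were 2.46 and 1.87 (adjusted p = 7.45e-08 and 1.02e-09, but 0.54 and 0.566 with an estimated correlation). The glutamate decarboxylase gene Gad1, which makes GABA, rose by 2.82 and 2.56, and the choline acetyltransferase gene ChAT by 3.34 and 2.57. All 14 sodium and calcium channel genes rose, with medians of 3.06 and 1.94 and the same counts adjusted over the list alone (adjusted p = 0.000167 and 4.25e-05, but 0.54 and 0.566 with an estimated correlation). The NALCN complex gene unc80 rose by 3.49 and 2.75 and the T-type calcium channel gene Ca-alpha1T by 3.15 and 2.71. Of 22 potassium channel genes, 19 rose and 2 fell against the driver control, and 20 rose and 2 fell against the UAS-APP control, also when adjusted over the list alone. Their medians were 2.25 and 1.44 (adjusted p = 0.00291 and 0.000452, but 0.54 and 0.566 with an estimated correlation). The Kv2 gene Shab rose by 2.94 and 2.22 and the EAG family gene Elk by 2.71 and 2.11, whereas the inward rectifier gene Irk1 fell (-1.41 and -0.95). Neuropeptide genes rose in 31 of 33 against the driver control and in 24 of 33 against the UAS-APP control, or 25 when adjusted over the list alone. The list medians were 1.83 and 0.65 (adjusted p = 0.000145 and 0.0191, but 0.54 and 0.68 with an estimated correlation). The peptide gene Nplp1 rose by 3.33 and 2.33 and the prohormone convertase gene amon by 2.74 and 1.77. CCHa2 (-3.29 and -2.01) and the adipokinetic hormone gene Akh (-2.78 and -3.46) fell.

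Calcium and cAMP signalling genes rose in 19 of 21 against either control, as they did when adjusted over the list alone, with medians of 1.13 and 0.93 (adjusted p = 0.000359 and 0.0002, but 0.54 and 0.566 with an estimated correlation). The calbindin gene Cbp53E rose by 2.60 and 1.79. Glial genes rose in 12 of 15 against either control, also adjusted over the list alone, with medians of 1.61 and 0.95 (adjusted p = 0.0382 and 0.00747, but 0.6 and 0.566 with an estimated correlation). With quantile normalization 3 glial genes fell against the driver control, where 1 fell. The glial transcription factor gene repo rose by 2.27 and 0.95, and the trehalose transporter gene Tret1-1 fell (-1.23 and -0.50). Photoreceptor genes rose in 25 of 25 against the driver control and in 20 of 25 against the UAS-APP control, also adjusted over the list alone, with medians of 2.71 and 0.65 (adjusted p = 1.63e-06 and 0.0071, but 0.54 and 0.682 with an estimated correlation). The visual G protein gene Gbeta76C rose by 2.54 and 0.95 and the retinal matrix gene eys by 2.52 and 2.12. With quantile normalization the photoreceptor medians were larger, 3.73 and 1.42, and 23 photoreceptor genes rose against the UAS-APP control. As deposited, the rhodopsin genes Rh4 (-0.64) and Rh6 (-0.62) fell against that control, and with quantile normalization Rh4 was higher (0.59) and Rh6 did not fall past the threshold (-0.22). Genes of the chemosensory appendages rose in 48 of 62 and 40 of 62, also adjusted over the list alone, and the list passed against the driver control alone (adjusted p = 0.0174 and 0.0742, and 0.407 and 0.566 with an estimated correlation). The odorant-binding protein genes Obp28a (2.46 and 1.69) and lush (2.29 and 1.60) rose. Of 20 genes related to the amyloid precursor and tau, 16 rose against the driver control and 14 against the UAS-APP control, and the list did not pass (adjusted p = 0.0671 and 0.0616). The adaptor gene X11Lbeta rose by 2.87 and 1.96, and the protease gene Bace fell (-7.19 and -4.92).

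Gut genes fell in 30 of 30 against the driver control and in 24 of 30 against the UAS-APP control, also adjusted over the list alone, with medians of -5.78 and -3.94. The list passed against both (adjusted p = 4.31e-19 and 1.58e-12, but 0.169 and 0.313 with an estimated correlation). The list took 8.83% and 8.89% of the fragments in the driver control libraries, 3.84% and 4.15% in the UAS-APP control, and 0.14% in each elav-Gal4 UAS-APP library. The serine protease gene Jon99Ci (-7.63 and -6.52), the amylase gene Amy-d (-7.93 and -5.96) and the protease gene yip7 (-8.17 and -6.25) fell. Amy-d, Jon99Ci and the trypsin genes have near-identical neighbours, so their single values are uncertain. Fat body genes fell in 11 of 14 and 9 of 14, also adjusted over the list alone, with medians of -2.08 and -0.85 (adjusted p = 8.51e-05 and 0.00437, but 0.54 and 0.566 with an estimated correlation). The list did not pass against the UAS-APP control with quantile normalization (adjusted p = 0.165), and the counts became 3 up and 10 down, and 4 up and 8 down, where they were 1 up and 11 down, and 1 up and 9 down. The storage protein gene Lsp1beta (-2.55 and -5.33) and the feeding-related gene fit (-4.10 and -4.85) fell, and Apoltp rose. Lipid synthesis and storage genes fell in 12 of 18 against either control, also adjusted over the list alone (adjusted p = 0.000255 and 0.00876, but 0.54 and 0.566 with an estimated correlation). The list passed with quantile normalization against neither control (adjusted p = 0.0568 and 0.218), and 5 of its genes rose and 10 fell against the UAS-APP control, where 1 rose and 12 fell. The lipase gene mag fell (-5.93 and -2.92), as did the perilipin gene Lsd-1 (-1.91 and -1.43). UDP-glycosyltransferase genes fell in 20 of 27 and 17 of 27, also adjusted over the list alone (adjusted p = 6.45e-06 and 0.0012, but 0.212 and 0.49 with an estimated correlation). Glutathione and antioxidant genes fell in 29 of 44 against either control, also adjusted over the list alone (adjusted p = 3.3e-05 and 0.0001, but 0.54 and 0.566 with an estimated correlation). With quantile normalization 3 UDP-glycosyltransferase genes rose against the driver control, where 7 rose. The transferase genes Ugt303B3 (-5.13 and -3.47) and GstE8 (-2.83 and -2.45) fell. Cytochrome P450 genes rose in 21 and fell in 35 of 64 against the driver control, also adjusted over the list alone (adjusted p = 0.000616, but 0.54 with an estimated correlation), and did not pass as a list against the UAS-APP control (adjusted p = 0.0842). With quantile normalization 14 P450 genes rose and 38 fell against the driver control.

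All 76 cytosolic ribosomal protein genes fell against both controls, also adjusted over the list alone, with medians of -1.76 and -1.67 (adjusted p = 9.22e-26 and 8.22e-25, but 0.54 and 0.566 with an estimated correlation). With quantile normalization the medians were smaller, -0.27 and -0.50, and 12 and 5 of the genes were higher. RpS20 changed by -2.30 and -2.34. Proteasome genes fell in 27 of 32 against either control, also adjusted over the list alone, with medians of -0.87 and -0.66 (adjusted p = 2.46e-07 and 4.25e-07, but 0.54 and 0.566 with an estimated correlation). The core subunit gene Prosalpha1 changed by -2.44 and -1.74, the largest fall of the list against the driver control. It was weakly expressed, at 0.880 FPKM against 6.61 in the driver control. The core subunit gene Prosbeta1 stood at 57.7 against 134.8 FPKM there, a log2 change of -1.64. Endoplasmic reticulum stress genes fell in 11 of 19 against either control, also adjusted over the list alone (adjusted p = 0.0226 and 0.0109, but 0.514 and 0.566 with an estimated correlation). The chaperone genes Gp93 (-1.73 and -2.13) and Hsc70-3 (-1.61 and -1.71) fell. Under quantile normalization this list did not pass against the driver control (5 up and 10 down, adjusted p = 0.122), and 4 of its genes rose and 12 fell against the UAS-APP control, where 6 rose and 11 fell. Oxidative phosphorylation genes fell in 35 and 33 of 62 and rose in 10 against either control, or 8 rose and 35 fell against the driver control when adjusted over the list alone, but the direction depended on the scaling. As deposited the list passed as lower (adjusted p = 2.02e-05 and 0.00108, but 0.607 and 0.682 with an estimated correlation). Its medians of -0.72 and -0.42 became 0.33 and 0.24 with quantile normalization, with 38 and 39 genes higher, and there the list passed as higher (adjusted p = 0.00606 and 0.0112). Genes of the mitochondrial genome fell in 10 of 14 against either control, also adjusted over the list alone (adjusted p = 0.00193 and 0.00966, but 0.54 and 0.634 with an estimated correlation). With quantile normalization that list did not pass, with 6 up and 4 down, and 4 up and 5 down, and mt:Cyt-b (-1.49) was higher against the driver control (0.73).

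Humoral immune effector genes fell in 32 of 41 against the driver control, also adjusted over the list alone (median -1.34, adjusted p = 5.85e-08, but 0.257 with an estimated correlation). Against the UAS-APP control 14 rose and 17 fell, and the list did not pass (adjusted p = 0.143). The immune-induced peptide gene BomT2 fell (-4.45 and -1.89), whereas AttB, DptA, Def and SPH93 rose against the driver control. Listericin passed as higher in the deposited values, but stood at -0.07 relative to the median of all genes. AttB has the near-identical neighbour AttA, so its value is uncertain. Autophagy genes passed as a list against the UAS-APP control with 20 of 26 up, also adjusted over the list alone (median 0.28, adjusted p = 0.0191, but 0.566 with an estimated correlation). They did not pass there with quantile normalization (13 up and 4 down, adjusted p = 0.0729), nor against the driver control, where the median of -0.05 and the upward list test differed in sign. Activity-regulated genes rose in 11 of 15 and 10 of 15, also adjusted over the list alone, without passing as a list (adjusted p = 0.214 and 0.242), and the capsid-like gene Arc1 fell (-1.48 and -3.07). The lists of immune signalling, heat shock and chaperone, glycolysis, circadian clock, muscle, hemocyte, male reproductive, female and cuticle genes passed against neither control. With quantile normalization glycolysis rose against both controls (adjusted p = 0.00258 and 0.00156), and heat shock and chaperone genes (adjusted p = 0.00415) and muscle genes (adjusted p = 0.0141) rose against the UAS-APP control. Immune signalling genes were lower against the driver control (adjusted p = 0.0477), amyloid precursor and tau related genes higher against it (14 up and 5 down, adjusted p = 0.0336) and chemosensory genes higher against the UAS-APP control (adjusted p = 0.0112), all with quantile normalization.

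Of 9866 tested genes, 8291 passed the threshold against the driver control (5578 up and 2713 down) and 7572 against the UAS-APP control (4546 up and 3026 down). Against both controls with one sign, 4280 genes rose and 2253 fell, 6533 in all, of which 2564 changed at least 2-fold. In 50 simulations of unchanged groups that share the elav-Gal4 UAS-APP libraries, limma called 0 such genes at most. At an unadjusted p under 0.05 the simulations gave 113.8 genes on average, against 6642 observed. The simulations drew independent noise for each gene and library, without differences of line or tissue. They address only the shared libraries and cannot tell an effect of APP from such differences. The share that rose depended on scaling. It was 65.5% of the 6533 genes as deposited, 44.5% with median centring and 52.4% with quantile normalization. Against the driver control alone it was 67.3%, 44% and 50.7%, and against the UAS-APP control 60%, 45.6% and 52.1%. Both comparisons use the elav-Gal4 UAS-APP libraries and are not independent of each other.

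The most raised genes against both controls included Crg-1 (X, 3793223 to 3797339), a forkhead family gene, at 24.8 and 26.9 FPKM in the elav-Gal4 UAS-APP libraries, 0 and 0.0413 in the driver control and 0.0831 and 0.0462 in the UAS-APP control. The noncoding RNA gene lncRNA:CR46123 was listed at 20.2 and 20.1 FPKM in elav-Gal4 UAS-APP, and at 0 and 0 in the driver control and 0 and 0 in the UAS-APP control. The cilium genes IFT54 (2.93 and 3.03) and Cep164 (3.85 and 2.87), the esterase gene Jhedup (3.57 and 3.01), and CG10357, CG4962, CG10185 and CG31528 completed this set. The most lowered genes besides those of the gut list were CG15263 (-8.41 and -7.87), CG3739, CG43055, CG5107 and CG4363. For genes that overlap or lie antisense to others the values are uncertain, since the library protocol does not state strand marking.

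The control lines of the APP table differed from each other in 6545 genes (1594 up and 4951 down in the driver control, median of all genes -0.27). The share up was 24.4% as deposited, 55.3% with median centring and 47.2% with quantile normalization. Relative to the median, gut genes were higher in the driver control (1.39, 26 of 30 up) and humoral immune effector genes too (1.46, 32 of 41 up), also adjusted over the list alone. Neuron (-1.51), photoreceptor (-2.02) and synaptic vesicle release genes (-1.13) were lower, with 13 of 13, 25 of 25 and 28 of 28 down, also adjusted over the list alone. The adjusted p of these 5 lists with an estimated correlation was 0.0863 for the first pair and 0.524 for the others. The yolk protein gene Yp2 (X, 10050951 to 10052636) was most raised, at 148 ± 3.78 against 0.298 ± 0.0249 FPKM, and the protease genes Jon99Fii (6.51) and Jon25Biii (4.45) rose too. Jon65Ai was listed at 22.1 and 24.2 FPKM in the driver control libraries and at 0 and 0 in the UAS-APP control. The protease-like genes CG8329 (-6.95) and CG3088 (-5.28), the cuticle gene Cpr72Ec (-5.13) and the odorant-binding protein gene Obp56g (-4.30) were lower. The dosage compensation RNA lncRNA:roX2 stood at 7.40 and 6.88 FPKM in the driver control libraries and at 50.4 and 47.4 in the UAS-APP control.

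**Figure D2:**
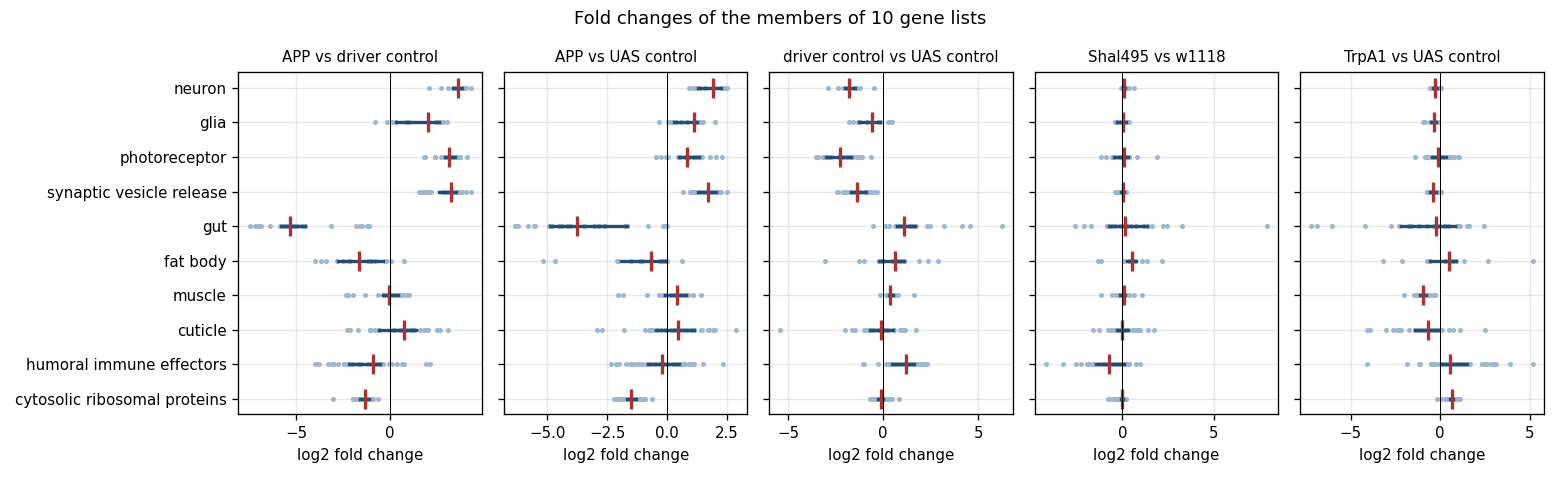
Log2 fold changes of the members of 10 gene lists (vertical axis) in 5 comparisons, as deposited, with 1 point per gene, a thick bar from lower to upper quartile and a red tick at the median. Gut genes lie at a median of -5.35 and -3.77 in elav-Gal4 UAS-APP against the driver and UAS-APP controls, and neuron genes at 3.62 and 1.91, with the same directions under median centring and quantile normalization.

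The Shal495 comparison asks which transcripts differ in the channel mutant from w1118. Yolk protein genes rose and humoral immune effector genes were lower as a list, while single trypsin and cytochrome P450 genes went both ways. The immune list call was lost with an estimated correlation (adjusted p = 0.759). Yp2 stood at 332 ± 27.3 against 1.00 ± 0.0648 FPKM in Shal495 against w1118, a log2 change of 7.38 ± 0.101 (adjusted p = 0.000147). The antibacterial peptide gene AttB stood at 0.530 ± 0.218 against 26.4 ± 0.0745 FPKM, a log2 change of -4.17 ± 0.152 (adjusted p = 0.00141), uncertain because of its near-identical neighbour AttA. Of 9628 tested genes, 112 rose and 116 fell, 228 in all, of which 164 changed at least 2-fold, and the median of all genes was -0.07. The share up was 49.1% as deposited, 54.5% with median centring and 57.4% with quantile normalization. The count rested on single libraries. It was 87 without w1118 replicate 1, 130 without w1118 replicate 2, 33 without Shal495 replicate 1 and 9 without Shal495 replicate 2, and 71, 84, 24 and 9 of these were among the 228. Shal495 replicate 2 is the library whose genotype label reads Shal496, so the comparison assumes that this label is a typing error.

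The trypsin gene betaTry (2R, 11346325 to 11347395) was listed at 298 and 191 FPKM in the Shal495 libraries and at 0 and 0 in the w1118 libraries, and epsilonTry at 7.30 and 10.1 and 0 and 0. Other raised genes were Yp1 (4.83 ± 0.123), the glucosidase-like gene tobi (4.81 ± 0.23), sordd2 (5.08 ± 0.141), CG14456 (5.54 ± 0.202), CG32640 (3.80 ± 0.192) and CG4962 (4.67 ± 0.336). CG4962 did not pass without the filter on low values or with voom. Lowered genes included CG18628 (-6.28 ± 0.144), Crg-1 (-4.21 ± 0.153), lncRNA:CR46123 (-4.07 ± 0.192), CG32523 (-4.12 ± 0.161), CG12934, CG9150, CG13794 and whe. The cytochrome P450 gene Cyp4p2 rose (5.04), with Cyp12c1, Cyp9h1, Cyp6a13 and Cyp6a14, while Cyp6a17 (-4.35), Cyp6a20 and Cyp9f3 fell. That made 5 up and 3 down of 62, or 9 and 9 adjusted over the list alone, and the list did not pass (adjusted p = 0.0782). Cyp6a17 did not pass with pseudocount 0.1 or without the filter.

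Humoral immune effector genes fell in 7 of 39 (3 with voom) and none rose, or 13 fell and 2 rose adjusted over the list alone, with a median of -0.73 (adjusted p = 0.0145, but 0.759 with an estimated correlation). The cecropin gene CecA2 (-2.54 ± 0.206), AttA (-1.89 ± 0.204) and the stress-induced gene TotM (-2.27 ± 0.266) fell, but none of these passed without Shal495 replicate 1 or without Shal495 replicate 2. Neuropeptide genes were higher as a list, with a median of 0.27 and 2 of 34 up, or 7 up and 1 down adjusted over the list alone (adjusted p = 4.89e-05, but 0.759 with an estimated correlation). Those were Akh (0.85, adjusted p = 0.0432) and the insulin-like peptide gene Ilp5 (1.20, adjusted p = 0.0459), and neither passed with voom or when any 1 of the 4 libraries was left out. The female list had 3 up (Yp1, Yp2 and Yp3) and 1 down (Cp19) of 8, or 3 and 2 adjusted over the list alone. It passed the list test at adjusted p = 0.0473, but not with quantile normalization (0.124), the replicate number as a block (0.0686) or an estimated correlation (adjusted p = 0.759 with an estimated correlation). Without Cp110 and Cp190, centrosomal genes that entered by their symbols, 3 of 6 were up and 1 was down, and the list passed at adjusted p = 0.00218 with limma's camera.

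Lists could pass with few single genes past the threshold, because the list test compares all members with the other genes. Most list calls in Shal495 were lost without Shal495 replicate 2, the library whose genotype label reads Shal496. Sodium and calcium channel genes (median 0.13), neuron genes (0.08) and oxidative phosphorylation genes (0.06) were higher with 0 genes past the threshold in limma, with voom or adjusted over the list alone, and 2, 2 and 6 at an unadjusted p under 0.05 (2 up, 2 up, and 2 up and 4 down, adjusted p = 0.00757, 0.0191 and 0.0135, but 0.853, 0.759 and 0.853 with an estimated correlation). Mitochondrial genome (median 0.23), lipid synthesis and storage (0.28) and fat body genes (0.54) were higher too, with 0 genes past the threshold over all genes in limma or voom, 4, 5 and 8 at an unadjusted p under 0.05 (3, 4 and 6 up, and 1, 1 and 2 down), and 2, 1 and 3 up and 1, 0 and 2 down adjusted over the list alone. Their adjusted p was 0.00703, 0.00677 and 0.0102, but 0.853, 0.759 and 0.759 with an estimated correlation. Proteasome genes were lower (median -0.15, 0 past the threshold in limma, with voom or adjusted over the list alone and 9 down at an unadjusted p under 0.05, adjusted p = 0.00231, but 0.759 with an estimated correlation). Under quantile normalization the mitochondrial genome, oxidative phosphorylation and neuron lists did not pass (adjusted p = 0.205, 0.24 and 0.0578). Of 22 potassium channel, 28 synaptic vesicle release and 44 transmitter genes, 0 passed in limma, with voom or adjusted over the list alone, and 8, 4 and 7 lay at an unadjusted p under 0.05. Their lists did not pass either (adjusted p = 0.837, 0.554 and 0.268).

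Gut genes rose in 4 of 22 (betaTry, epsilonTry, Jon25Bii and Mal-A7) and fell in 3 (thetaTry, gammaTry and deltaTry), or 8 and 5 adjusted over the list alone, without passing as a list (adjusted p = 0.0804). The odorant-binding protein genes Obp49a, Obp59a, Obp19b and Obp8a fell, 4 of 80 chemosensory genes, or 8 down and 2 up adjusted over the list alone. The rhodopsin gene Rh5 rose (1.90) and chp fell, the flight muscle actin gene Act88F rose (1.10), and the hemocyte scavenger receptor gene Sr-CI fell (-1.89). Among stress and detoxification genes GstE14 and Ugt36F1 rose, as did the recognition protein gene GNBP1, and GstE4, Ugt35C1, Ugt36E1 and the small heat shock gene Hsp67Bc fell. Of these Obp49a, Obp19b, Obp8a, GstE14, Ugt36F1, GNBP1, Ugt35C1 and Hsp67Bc, and the P450 genes Cyp12c1, Cyp6a13, Cyp6a14 and Cyp9f3, did not pass whichever of the 4 libraries was left out. Not passing in 3 of these 4 fits were thetaTry, Mal-A7, Obp59a, chp, Act88F, GstE4 and Ugt36E1, and in 2 of them Jon25Bii, Sr-CI, Cyp9h1 and whe. The genes gammaTry, deltaTry and Cp19 could be tested in 2 of the fits and passed in neither. The remaining lists did not pass, among them ribosomal proteins with 0 of 77 past the threshold in limma or voom and 4 at an unadjusted p under 0.05 (adjusted p = 0.899), glycolysis (adjusted p = 0.159), circadian clock (adjusted p = 0.359) and activity-regulated genes (adjusted p = 0.872).

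The TrpA1 comparison asks which transcripts differ when the driver is added to UAS-TrpA1, so that the driver line is part of the difference. Ribosomal protein, immune effector and fat body genes were higher, and muscle, synaptic, oxidative phosphorylation and yolk protein genes lower. Every list call of the TrpA1 comparison was lost with an estimated correlation (adjusted p of 0.299 or more), and that of the fat body list, with 4 of 13 genes down, also with quantile normalization (adjusted p = 0.0509). The antibacterial peptide gene DptA (2R, 18865765 to 18866260) stood at 140.2 ± 1.12 against 2.94 ± 0.000240 FPKM in elav-Gal4 UAS-TrpA1 against the control, a log2 change of 5.33 ± 0.046 (adjusted p = 2.44e-08). Yp2 stood at 0.193 ± 0.0906 against 399 ± 7.36 FPKM, a log2 change of -8.23 ± 0.065 (adjusted p = 1.97e-08). Of 8980 tested genes, 1495 rose and 3944 fell, 5439 in all, of which 556 changed at least 2-fold. The median of all genes was -0.16 and is taken away from the log2 changes of genes and lists here. The share up was 27.5% as deposited, 55.9% with median centring and 51.7% with quantile normalization.

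Ribosomal protein genes rose in 74 of 76, or 74 up and 1 down adjusted over the list alone, with a median of 0.80 (adjusted p = 4.56e-42, but 0.299 with an estimated correlation). RpS29 (1.28), RpS23 (1.18) and RpS20 (1.17) rose, and RpL41 and RpS15Ab did not pass. With quantile normalization the median was smaller, 0.29, and 61 rose and 2 fell. Humoral immune effector genes rose in 29 and fell in 9 of 42, or 30 and 9 adjusted over the list alone, with a median of 0.71 (adjusted p = 2.05e-10, but 0.299 with an estimated correlation). DptB rose by 4.06, Dro by 3.28 and AttC by 2.78. Fat body genes rose in 9 and fell in 4 of 13, also adjusted over the list alone (median 0.64, adjusted p = 0.00306, but 0.299 with an estimated correlation), and did not pass with quantile normalization (adjusted p = 0.0509). Lsp1beta rose by 5.33, Obp99b by 2.83 and the inositol oxygenase gene Miox by 1.04, whereas Lsp1gamma, Obp99a, to and bgm fell. Lipid synthesis and storage genes rose in 12 and fell in 3 of 18, also adjusted over the list alone, with the fatty acid synthase gene FASN1 at 0.93 (adjusted p = 1.77e-05, but 0.299 with an estimated correlation). Those that fell were mag, mdy and yip2, and yip2 lay above the median shift (0.04).

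Muscle genes fell in 20 of 20, also adjusted over the list alone, with a median of -0.81 (adjusted p = 6.89e-08, but 0.299 with an estimated correlation). The myosin light chain gene Mlc2 (-1.22) and the actin gene Act79B (-1.30) fell. Oxidative phosphorylation genes fell in 56 of 60, also adjusted over the list alone (median -0.27, adjusted p = 2.48e-10, but 0.354 with an estimated correlation), with the ATP synthase gene ATPsynbeta at -0.59. Glycolysis genes fell in 12 of 14, also adjusted over the list alone (adjusted p = 0.0164, but 0.421 with an estimated correlation), with Gapdh1 at -0.74, while Tps1 and Treh rose. Synaptic vesicle release genes fell in 24 of 28, or 26 adjusted over the list alone (median -0.25, adjusted p = 0.000937, but 0.299 with an estimated correlation). The genes comt (-0.59) and shi (-0.58) fell, and nSyb, Rab3-GEF, Syn and VGlut did not pass. Transmitter genes fell in 32 of 42, or 33 adjusted over the list alone (adjusted p = 0.00238, but 0.299 with an estimated correlation). The synthesis genes ple (-1.49) and Gad1 (-0.94) fell, and nAChRalpha6 rose. Calcium and cAMP signalling genes fell in 16 of 21, or 17 adjusted over the list alone (adjusted p = 0.00863, but 0.299 with an estimated correlation), with the calcium pump gene SERCA at -1.03. Glial genes fell in 12 of 15, or 13 adjusted over the list alone (adjusted p = 0.00362, but 0.299 with an estimated correlation), with the GABA transporter gene Gat at -0.73. With quantile normalization fewer genes of these 4 lists fell, 15 synaptic vesicle release, 19 transmitter, 11 calcium and cAMP signalling and 9 glial genes, and the lists still passed (adjusted p = 0.000485, 0.00196, 0.00638 and 0.0015).

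Activity-regulated genes rose in 8 and fell in 3 of 15, also adjusted over the list alone (median 0.37, adjusted p = 0.00436, but 0.421 with an estimated correlation). Arc1 rose by 1.84 ± 0.051 and cbt by 0.56 ± 0.043, and CG17778, CrebB and CrebA fell as deposited, whereas 9 rose and none fell past the threshold with quantile normalization. Heat shock and chaperone genes rose in 6 and fell in 5 of 14, also adjusted over the list alone (adjusted p = 0.0448, but 0.354 with an estimated correlation). Hsp26 rose by 1.32 and Hsp23 by 1.27. The list test did not pass with quantile normalization (8 up and 3 down, adjusted p = 0.135) or with the replicate number as a block (adjusted p = 0.0556). Cytochrome P450 genes rose in 18 and fell in 18 of 59, also adjusted over the list alone, and passed as higher than the other genes (adjusted p = 0.00863, but 0.421 with an estimated correlation), with 29 up and 14 down under quantile normalization. Cuticle genes fell in 21 of 33, also adjusted over the list alone (median -0.50, adjusted p = 0.0116, but 0.299 with an estimated correlation), with Cpr100A at -3.94. In the female list 5 of 6 fell, also adjusted over the list alone (adjusted p = 0.0116, but 0.421 with an estimated correlation), namely Yp1, Yp2, Yp3, Cp190 and Cp19, and 4 fell with quantile normalization. Cp110 and Cp190 are centrosomal genes that entered the list by their symbols, and without them 4 of 4 fell, too few genes for a list test. Among single genes CAH5 (4.38), Obp56a (3.46), CG15263, CG45045, CG42728, Cda9 and CG8329 rose most. CG7214 (-8.64), Acp1 (-7.30), Jon25Bi (-7.04), Bace (-6.79), Jon25Bii, CG8736, CG18404 and Pebp1 fell most. The trypsin gene thetaTry was listed at 0 and 0 FPKM in elav-Gal4 UAS-TrpA1 and at 63.4 and 68.3 in the control. The potassium channel, sodium and calcium channel and neuron lists did not pass (adjusted p = 0.228, 0.0554 and 0.149), nor did gut, circadian clock, neuropeptide and the other lists. The mitochondrial genome list was lower with quantile normalization (adjusted p = 0.00627), and the photoreceptor gene ninaE, at 0.92 otherwise, showed no difference (0.00).

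**Figure D3:**
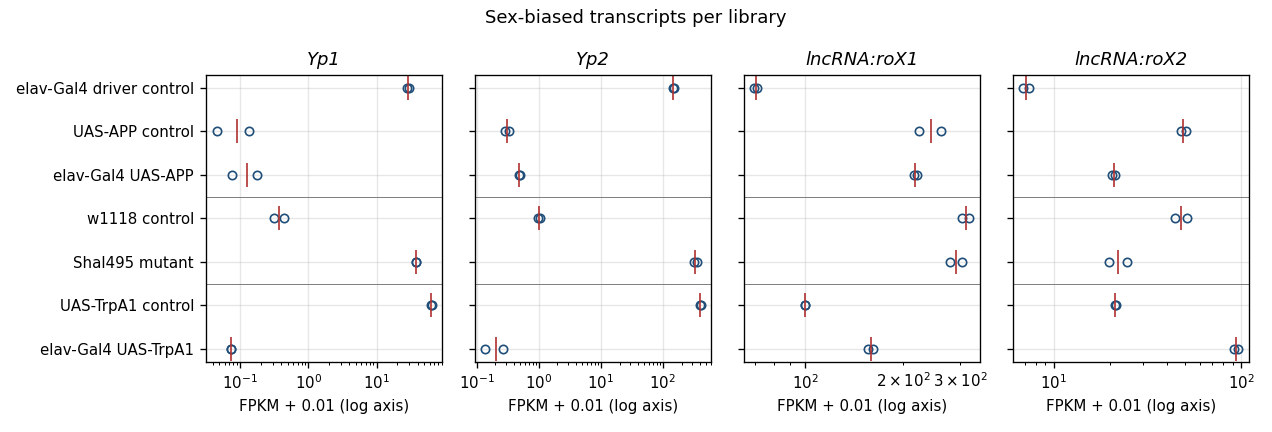
FPKM plus 0.01 of Yp1, Yp2, lncRNA:roX1 and lncRNA:roX2 on a log axis, with 1 point per library, grouped by genotype, and a red tick at each group mean. Yp2 stands at 145.0 and 150.4 FPKM in the driver control, at 313 and 351 in Shal495 and at 393 and 404 in the UAS-TrpA1 control, and levels are not comparable across the 3 tables.

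Shared responses were counted among genes tested in both fits. Shal495 and TrpA1 shared 29 raised genes where 17.3 were expected by chance (one-sided Fisher exact p = 0.00257) and 45 lowered genes where 46.1 were expected (p = 0.626). Opposite directions were as frequent, with 30 genes down in Shal495 and up with TrpA1 where 17.3 were expected (one-sided Fisher exact p = 0.00122) and 49 the other way where 46.1 were expected (p = 0.319). Shal495 and APP shared 31 raised genes where 46.8 were expected (one-sided Fisher exact p = 0.999) and 38 lowered genes where 24.3 were expected (p = 0.00177). A further 46 genes rose in Shal495 and fell with APP where 23 were expected (Fisher exact p = 3.76e-07), and 38 went the other way where 49.5 were expected (p = 0.99). TrpA1 and APP shared 173 raised genes where 620.3 were expected and 727 lowered genes where 933.1 were expected (Fisher exact p = 1 for each). Opposite directions prevailed, with 704 genes up with TrpA1 and down with APP where 353.1 were expected (Fisher exact p = 2.34e-108), and 2221 the other way where 1639.2 were expected (p = 5.76e-141). These are Fisher exact tests over genes, which are not independent replicates. The shared counts with Shal495 rested on its libraries. Genes with one sign numbered 28, 39, 9 and 2 with TrpA1, and 17, 42, 5 and 1 with APP, without w1118 replicate 1, w1118 replicate 2, Shal495 replicate 1 and Shal495 replicate 2 in turn.

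Called genes lay unevenly on the chromosome arms in some comparisons. On chromosome 4, 87 of 91 tested genes passed against the driver control (odds ratio 4.16, two-sided Fisher exact, adjusted p = 0.00774) and 77 of 91 against both controls (odds ratio 2.83, adjusted p = 0.000744). In the TrpA1 comparison genes on X passed less often, 56.17% against 61.42% elsewhere (odds ratio 0.81, adjusted p = 0.00119). In Shal495, 98 of 4260 tested genes on chromosome 3 passed (2.3%), where Shal lies, against 130 of 5351 elsewhere (2.43%, odds ratio 0.95, 95% interval 0.72 to 1.24, Fisher exact p = 0.686).

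The authors also deposited enrichment tables of their own changed genes, whose contrasts and thresholds are not given in the sources used here. In the authors' deposited APP table the KEGG pathway Ribosome held 84 genes (p = 7.2e-12) and Protein export 12 (p = 0.00055), and the GO term cilium held 19 (p = 2.85e-07) and neuropeptide receptor activity 18 (p = 4.18e-06). In the Shal495 tables the authors' p was 1.5e-08 for the GO term extracellular region with 53 genes, and 1.59e-06 for the KEGG pathway Glycolysis / Gluconeogenesis with 10 genes. Of these the authors listed 21 as up and 32 as down, and 2 as up and 8 as down. In the TrpA1 tables it was 4.98e-16 for extracellular region with 91 genes, listed as 44 up and 47 down, and 7.69e-07 for Starch and sucrose metabolism with 10 genes. The authors' GO table of Shal495 listed 97 genes as up, of which 96 were tested here, all were higher and 47 passed. It listed 176 as down, of which 91 were tested, all were lower and 37 passed. For TrpA1 196 of 212 listed as up and 202 of 237 listed as down were tested, and every one tested passed in the same direction. The authors' directions and the values tested here come from the same series, so the shared directions give no independent support.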

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

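For the first pattern the tests were chosen only after the result was seen. For the second this holds for the test of fat body RNA and for the comparison of Cyp4d21 with elav-Gal4 UAS-APP, and for the third for the test of females among the mutants. For the gene lists compared between the transgenes, the condition that the sign also holds relative to the median of all genes was added after seeing the values. Log2 values of the 3 patterns are as deposited unless they are said to be relative to the median of all genes.

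The medians of 19 gene lists lay in opposite directions on adding elav-Gal4 to UAS-APP and to UAS-TrpA1, in every pair of libraries, as deposited and relative to the median of all genes. Of these lists 7 passed the list test in both comparisons, 9 in 1 of them and 3 in neither (hemocyte, male reproductive, and amyloid precursor and tau related), and none passed with an estimated correlation. The difference between these effects was not tested, and the transgenes were measured in separate tables that share no group. The lists that were higher with APP and lower with TrpA1 differed by 1.68 (potassium channels), 2.06 (sodium and calcium channels), 1.78 (synaptic vesicle release), 2.19 (transmitter receptors and synthesis), 0.66 (neuropeptides), 0.31 (autophagy), 0.90 (amyloid precursor and tau related), 1.09 (calcium and cAMP signalling), 1.86 (neuron), 1.11 (glia), 1.08 (muscle), 2.94 (female) and 0.74 (cuticle) in log2 median. Several of these lists lay near the median of all genes with TrpA1. Neuropeptides stood at -0.01, autophagy at -0.05, amyloid precursor and tau related at -0.1, neuron at -0.13 and potassium channels at -0.18. With APP these lists stood at 0.65, 0.25, 0.8, 1.74 and 1.5. The fall with TrpA1 exceeded the rise with APP for muscle (-0.82 and 0.26), cuticle (-0.43 and 0.31) and female genes (-2.73 and 0.22). The female list holds the centrosomal genes Cp110 and Cp190, matched by their symbols, and without them only 4 of its genes were tested with TrpA1. Lists that were lower with APP and higher with TrpA1 differed by -1.06 (humoral immune effectors), -2.46 (cytosolic ribosomal proteins), -0.98 (lipid synthesis and storage), -1.74 (fat body), -0.73 (hemocyte) and -0.91 (male reproductive). The size for ribosomal proteins depended on scaling, since with quantile normalization their medians were -0.5 with APP and 0.29 with TrpA1.

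Gut genes were lower and neuron genes higher in elav-Gal4 UAS-APP than in both controls. A smaller share of gut RNA alone would raise the genes of all other cell types alike. Against the UAS-APP control the medians of neuron and photoreceptor genes differed by 1.09 (quartiles 1.29 to 2.26 and 0.51 to 1.33, permutation p = 5e-05 over 100000 permutations of genes, which are not independent). With quantile normalization these medians lay closer, at 2.12 and 1.42, and were not permuted. Against the driver control neuron and photoreceptor medians differed by only 0.48, and with quantile normalization the order turned (3.44 and 3.73). Neuron and glial genes differed there by 1.58 with a wide spread (glial quartiles 0.30 to 2.63), so neither list decides anything against that control. Neuron and muscle genes, compared after the photoreceptor and glial lists had left this open, differed there by 3.70 (quartiles 3.38 to 3.84 and -0.38 to 0.43, permutation p = 1e-05), which argues against gut RNA alone unless muscle was lost with the gut. A separate question was whether a few abundant gut genes took counts from the others. Taking out the fragments of the gut list would raise other genes by at most 0.13 on the log2 scale. The list holds only a part of gut RNA, so this value sets no limit on the effect of all gut RNA. With quantile normalization the gut list still stood at -3.24 or lower and the neuron list at 2.12 or higher, which speaks against the authors' scaling as the cause. The combination of driver and transgene is not the only possible source, since the neuron list already differed by -1.78 between the controls (-1.51 relative to the median of all genes). The gut list took 8.83% and 8.89% of fragments in the driver control libraries and 3.84% and 4.15% in the UAS-APP control. These shares argue against brain or head alone as the tissue of those libraries. How much of the body, and which other tissue, went into each library stays open and untested.

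Yolk protein genes were high and lncRNA:roX2 low in the driver control, the Shal495 mutant and the UAS-TrpA1 control, although all labels say male. The other roX RNA, lncRNA:roX1, was lower in the driver and UAS-TrpA1 controls but overlapped between Shal495 (303.6 and 279.1 FPKM) and w1118 (320.1 and 303.1). Low lncRNA:roX2 did not go with high yolk protein genes alone, since elav-Gal4 UAS-APP had low yolk protein genes and stood at 20.53 and 21.28 FPKM of lncRNA:roX2, below the UAS-APP control (50.36 and 47.4). Females among the flies may be a source, and the test set in advance could not be run in full because the male-biased gene tsx has no value in the tables. No sex-biased genes beyond the 2 of that test were weighed. The other male-biased gene of the test, Cyp4d21, was lower in the driver control than in the UAS-APP control (-0.58). Cyp4d21 was also lower in Shal495 than in w1118 (-1.01) and in the UAS-TrpA1 control than in elav-Gal4 UAS-TrpA1 (-0.04, too small to decide). It stood at 161.0 and 68.57 FPKM in the Shal495 libraries and at 192.5 and 233.9 in the w1118 libraries. The size of -1.01 thus rested largely on Shal495 replicate 2, whose genotype label reads Shal496. Cyp4d21 was higher in the driver control than in elav-Gal4 UAS-APP (0.53), where yolk protein genes are low too, so females stay undecided. Relative to the median of all genes these 4 log2 differences were -0.31, -0.94, -0.21 and 0.96. More fat body RNA alone is argued against, since it would raise the other fat body genes about as much as the yolk protein genes. The median of the fat body list, which holds no yolk protein genes, was 0.62 (quartiles -0.20 to 1.08), 0.54 (0.27 to 0.77) and -0.48 (-0.88 to 0.59) in these 3 comparisons (0.89, 0.61 and -0.64 relative to the median of all genes), where the least raised of Yp1, Yp2 and Yp3 rose by 3.05, 3.20 and 4.81. The smallest gap was 2.43. A part of the rise from fat body RNA is not excluded. No biological explanation was tested.

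Genes that passed between Shal495 and w1118 could follow variation linked to the mutant chromosome, but genes on chromosome 3 did not pass more often (odds ratio 0.95, 95% interval 0.72 to 1.24, two-sided Fisher exact test). Background variation elsewhere in the genome was not tested, and it would also raise the share on the chromosomes that chromosome 3 was compared with. The odds ratio therefore does not exclude variation on chromosome 3. The gene w, listed on X, stood at 21.1 and 23.3 FPKM in Shal495 and at 0.122 and 0.0465 in w1118, and the cause was not tested. Females among the mutant flies remain undecided. Of 153 genes that also passed in the TrpA1 comparison, 79 (51.6%) went the way of the group with high yolk protein genes there, where the shares of raised genes alone would give 50.2%. The Shal mutation itself stays among the open explanations, since the design holds 1 mutant line and 1 control line.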

How the results depend on the processing

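Over all settings, named genes kept their side of the threshold in 8326 cases. They lost the threshold in 239, gained it in 34 and reversed in 12. A reversal is a change of sign in a gene that passed in either fit. Changes of sign in genes that passed in neither fit are among the 8326, as are other genes that never passed. Cases are single genes in a comparison under an alternative. With quantile normalization the log2 changes that reversed were Hsc70-4 (0.508), mt:Cyt-b (0.732), Pgi (0.126), Tps1 (0.132) and Tpi (0.415) against the driver control, and Tpi (0.2), Pglym78 (0.451) and Rh4 (0.59) against the UAS-APP control. With median centring w (-0.045) and Listericin (-0.203) reversed against the driver control and yip2 (0.067) with TrpA1, and without elav-Gal4 UAS-TrpA1 replicate 2 RpL41 reversed with TrpA1 (-0.125, with 0.235 as the highest value when other libraries were left out). Genes named after their values were seen are included. The cause of each reversal was not tested.

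Without a filter on low values 28 genes passed in Shal495, its overlaps with TrpA1 and APP fell to 8 and 2 genes, and the cause was not tested. With the replicate number as a block, which takes 1 residual degree of freedom, 96 genes passed in Shal495 and the overlaps were 30 with TrpA1 and 28 with APP. A fold minimum of 2 kept, by its construction, 4227 genes against the driver control, 2882 against the UAS-APP control, 1344 between the controls, 556 with TrpA1 and 2564 against both controls. With it the overlaps were 9 (Shal495 and TrpA1), 32 (Shal495 and APP) and 104 (TrpA1 and APP). Voom, chosen after seeing the data, gave an overlap of 44 genes between Shal495 and APP, and the cause was not tested. With quantile normalization 6 lists passed in Shal495 in place of 10. Without Cp110 and Cp190 in the female list and Acp65Aa in the male reproductive list, also chosen after seeing the data, 15 lists passed with TrpA1 in place of 16, because the female list became too small to test. With an estimated correlation 0 lists passed against the driver control, 0 against the UAS-APP control, 0 in Shal495 and 0 with TrpA1, with few residual degrees of freedom to estimate it.

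Leaving out 1 library moved the Shal495 results most. Its count of genes ran from 9 to 130, its overlap with TrpA1 from 2 to 72, its overlap with APP from 1 to 70 and its lists from 2 to 13, each lowest without Shal495 replicate 2. A group left with 1 library is assumed to vary like the other groups. The counts against the driver control, against the UAS-APP control, between the controls, against both and with TrpA1 stayed within 1.5 times their values under pseudocount 0.1, both filters, both scalings, the block, voom and each library left out. The chromosome arms that passed numbered 3, 4 with a fold minimum of 2, and 3 without genes within 2 Mb of Shal. A gene expressed in only 1 group could not be tested when a library of that group was left out, since it fell below the filter.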

Other observations

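Of 14 tested genes of the circadian clock list, 4 were at least 2-fold higher in FPKM + 1 in Shal495 replicate 1 than in replicate 2 and 1 was lower, with no such gene between the w1118 libraries, and the difference between single libraries was not tested. The clock gene tim stood at 224.5 FPKM in replicate 1 and 18.0 in replicate 2, and per at 54.6 and 15.1, while the w1118 libraries stood at 185.2 and 219.5 for tim and at 65.9 and 63.0 for per. Of 16 tested genes of the male reproductive list, 8 stood at least 2-fold higher in FPKM + 1 in w1118 replicate 1 than in each of the other 3 libraries of its table, also not tested. The sperm tail gene dj stood there at 14.3 FPKM and the testis tubulin gene betaTub85D at 24.2 FPKM, against 0.316 and 1.25 in w1118 replicate 2. Crg-1 stood near 25 FPKM in elav-Gal4 UAS-APP (24.8 and 26.9) and near 30 in w1118 (29.9 and 31.5). Of 22 genes under 1 FPKM in the 4 control libraries of the APP table and at 5 or more in both elav-Gal4 UAS-APP libraries, 10 were at 5 or more in both w1118 libraries, 6 in both Shal495 libraries, 1 in both UAS-TrpA1 control libraries and 0 in both elav-Gal4 UAS-TrpA1 libraries. These counts set levels side by side across separate tables that share no group. Among the 22 are the dopamine receptor gene Dop1R1, the ciliary dynein gene Dhc93AB and the cadherin gene stan.

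The elav-Gal4 driver line and its background may contribute to the genes that passed between elav-Gal4 UAS-TrpA1 and UAS-TrpA1 alone, a hypothesis set before its result was seen. Of 3703 genes that passed there and between the controls of the APP table, 2178 (58.8%) went the same way. The limits set in advance were over 60% for the hypothesis and 50% or less against it, and they did not allow for most genes being lower in both comparisons. The shares of raised genes alone would give 57.9%, so 58.8% decides nothing. With quantile normalization the share was 54.4% where 56% would be expected, and the hypothesis stays undecided.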
